A study of Homo sapiens with 2 samples.

How the data were processed

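Total RNA from THP-1 cells, a human monocytic leukaemia line, was measured in 2 samples, 1 treated with PBS and 1 with 100 nM CXCL14, both for 60 min. Per the labels, the RNA was amplified and labelled with Cy3, and each sample was hybridised to 1 Agilent array of 62976 spots. The groups were taken from the treatment given in the labels. Both arrays lay on the same slide and were scanned on the same day, so neither slide nor scan separates the groups, but each group holds 1 array and 1 culture.

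The deposited scanner files hold intensity values per spot on a linear scale. Per the file headers and the submitters' processing notes they were made with Agilent Feature Extraction 10.10.1.1, which subtracted the background and corrected spatial trends, and the array design is annotated to human build hg19. The flags for spots well above background, saturated or outlying come from the same software. Of the 10 quality measures that the headers grade, 9 were in range on the PBS array and 10 on the CXCL14 array. The mean net signal of negative controls was outside its range on the PBS array (40.4 intensity units, against 30.6 on the CXCL14 array). The deposited value table of the authors holds intensity values too: each column was the processed signal of that array times 1 factor, 2.27 for PBS and 2.31 for CXCL14. Its column medians were 98.4 and 83.0 units, its scale is linear, and how its factors were chosen is not given in the sources used here.

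From the processed signals, log2 values were averaged over the spots of a probe, after control spots and spots with a non-uniformity or population outlier flag on either array were left out, and each array's 75th percentile over 50585 probes was subtracted. Probes were named through their RefSeq accessions, without versions, in the RefSeq gene table of GRCh38.p14, which was used for names only because its build differs from that of the array. Of 29174 probes with such an accession 28162 were matched, which gave 20502 gene symbols, and 22416 probes stayed without a symbol. A gene was represented by its probe of highest mean level. It counted as measured where that probe was well above background on both arrays, as for 14560 genes, of which 4607 had several probes. For 5335 genes the probe was well above background on neither array. For the others a fold is a lower bound, the bright array's value against the higher of the dim probe's own value and the lowest signal well above background on the dim array (23.2 units for PBS and 17.5 for CXCL14).

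With 1 array per group no test was made. Genes were counted by size, at a log2 difference of 1 or more. Each of 24 gene lists fixed before the data were examined was described by its median and by the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean level. The genes named were fixed by rule before the data were examined. They are, per direction, up to 10 genes of largest difference at or above the 25th percentile of level, at least 2-fold or, failing that, 1.5-fold apart, and up to 3 bounds of at least 2-fold. To these the rule adds up to 4 measured members per list with the largest absolute difference, and *CXCL14*, *CXCR4*, *ACKR3* and *ACKR2* whatever their values. A few further list members were named after their values were seen, and some genes that the rule takes are not reported here.

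The technical error was estimated from probes spotted 10 times on each array, of which 653 were well above background on both. The SD of the log2 difference of a spot around its probe's mean was pooled in 4 classes of gene level that each hold 25% of the measured genes (0.28, 0.10, 0.09 and 0.09, from lowest to highest). The error model of Feature Extraction gives a median error of 0.15 on the log2 scale per spot on each array. Of 10 E1A spike-in control probes, 6 were well above background on both arrays, and they were 0.15 to 0.36 higher on the CXCL14 array after scaling, with a median of 0.32. Of 96 ERCC control probes, 8 were well above background, all at low levels, and their differences ran from -0.32 to -0.02 with a median of -0.16. Whether ERCC RNA was added to these samples is not given in the sources used here. The median difference over genes went from -0.06 in the lowest of these classes to 0.09 in the highest. The number of arrays limits the precision.

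The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling on the median of measured probes, a loess curve of the difference on level (span 0.3), scaling on all 14 measured spike-in controls, scaling on the 6 E1A controls alone (not planned), 4 other filters on dim genes (one of them no filter, with signals under 1 set to 1), the mean over a gene's probes, the authors' value table, outlying spots kept, and thresholds of 1.5-fold and 3-fold. The normexp correction used the median spot signal, as the mean spot signal is not among the columns used here. Arrays simulated at the levels of these 2 with 200 changed genes gave 49 of 50 genes changed 3-fold and 50 of 50 changed 4-fold at or above 2-fold, and 23 of 50 changed 2-fold. Of 14354 simulated unchanged genes 0 reached 2-fold. The noise added at low signal was smaller than the SD of these arrays' negative control spots (5.6 units for PBS and 5.9 for CXCL14). Of the real repeated spots, 3 lay at least 2-fold below and 4 at least 2-fold above their probe's mean difference. The 0 is therefore no estimate of false calls on these arrays. Of 200 simulated unshifted lists of 20 genes, 4 lay above the 97.5th percentile and 4 below the 2.5th. Their noise was independent between genes, so these shares do not hold for lists whose genes vary together. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.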

Results

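The question put by the design was which transcripts differed in THP-1 cells, a human monocytic leukaemia line, 60 min after 100 nM CXCL14, a secreted chemokine, compared with cells given phosphate-buffered saline (PBS) for 60 min. Total RNA of each culture was hybridised to 1 single-colour oligonucleotide array, so each group was 1 array and none of the differences below has a replicate check. On the PBS array 34455 of 58717 non-control spots (58.7%) were well above background, and on the CXCL14 array 34553 (58.8%). No spot was saturated. Of 20502 genes with a symbol, 14560 were measured on both arrays. Values are log2 signals relative to each array's 75th percentile, and differences are CXCL14 minus PBS.

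The immediate early genes, which mitogens and cytokines induce within minutes without new protein synthesis, had the list median furthest above that of random lists of their level (0.19 against 0.04). *EGR1*, a zinc finger transcription factor, had a signal of 2999 intensity units with PBS and 5457 with CXCL14, a difference of 0.96 (1.95-fold). Its relative *EGR2* was 1.11 higher (54 against 108 units), the dual-specificity phosphatases *DUSP5* and *DUSP1* were 0.92 and 0.65 higher, and *FOS*, a subunit of the AP-1 transcription factor, was 0.60 higher (1356 against 1914 units). The chemokine genes *CCL3* and *CCL4* were 0.66 and 0.46 higher. Beyond these genes the 2 arrays were close: 13 of 14560 measured genes were at least 2-fold higher with CXCL14, 26 were at least 2-fold lower, and 99.7% lay between. The log2 difference had an SD of 0.20 and a median of 0.04 over measured genes. As an estimate of error from the spots themselves, probes spotted 10 times gave an SD between spots of the same pair of arrays of 0.28 in the lowest 25% of gene levels, 0.10 in the next 25%, and 0.09 in both classes above. The error model of the scanner software gives a median error of 0.15 per spot on each array. Both cover the array only, not the cells, the RNA or the labelling, and *EGR2* and *DUSP5* were in the lowest class. In that class 12 genes (0.33%), *EGR2* among them, were at least 2-fold higher, and 4 of 1280 repeated spots (0.31%) deviated as far upward. *EGR2* and *DUSP5* dropped to 0.52 and 0.29 with normexp background correction and to 0.79 and 0.60 with E1A spike-in scaling. *EGR2* was then under 2-fold. *EGR1*, *EGR2*, *DUSP5*, *FOS*, *CCL3* and *CCL4* each rested on 1 spot per array, and *DUSP1* on 10.

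**Figure D1:**
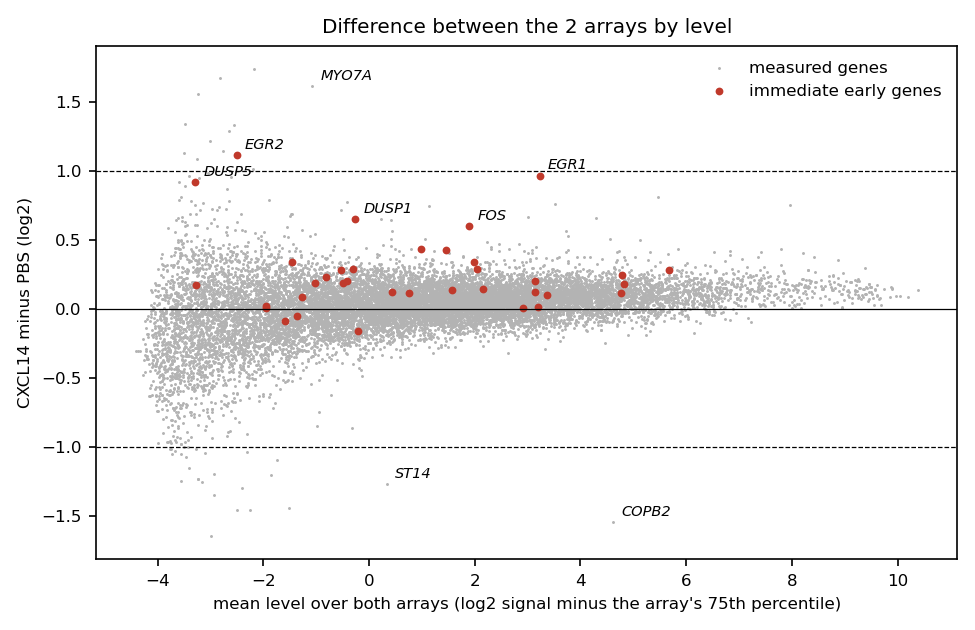
Each grey point is 1 of 14560 measured genes, with its mean level over both arrays on the x axis (log2 signal minus the array's 75th percentile) and CXCL14 minus PBS on the y axis (log2), red points are the 36 measured immediate early genes, and dashed lines mark 2-fold. The points fan out at low level, *EGR1* lies at 0.96 among bright genes, and *COPB2* and *ST14* lie at -1.54 and -1.27.

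The split between higher and lower genes depended on the scaling. The 13 higher and 26 lower genes became 20 and 15 with quantile normalization, 20 and 16 with a level-dependent scaling, 12 and 42 in the authors' value table, and 6 and 123 when the arrays were set to the median of their 6 measured E1A spike-in controls, which moved the median over measured genes by -0.32. All 6 of these E1A controls were higher on the CXCL14 array, while the 8 measured ERCC controls, of 96, were lower. The ERCC controls were all at low levels, and whether ERCC RNA was added is not known, so they may not act as spike-ins. With all 14 controls the median moved by 0.03 and the counts were 14 and 22. Most of these genes were dim: of the genes at or above the 25th percentile of level, 1 was at least 2-fold higher and 2 were at least 2-fold lower.

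Among the genes at or above that level, *MYO7A*, which encodes an unconventional myosin, was 1.61 higher (121 against 345 units), but a further probe of this gene gave 0.13 and the mean over its probes was under 2-fold. The next genes by size were under 2-fold: *EGR1*, the histone gene *H3C3* (0.81), *C2orf74-DT* (0.77, with -0.09 from another probe), *CHMP4A* of the ESCRT-III membrane scission machinery (0.76), the minor spliceosome RNA *RNU4ATAC* (0.75), the chemokine gene *CCL3L3* (0.75, with 0.46 from another probe), the small nucleolar RNAs *SNORA19* and *SNORA27* (0.71 and 0.67) and *CCL3* (0.66). *CCL3* and *CCL3L3* are near-identical copies whose transcripts the probes may not separate. In the other direction, *COPB2*, a subunit of the COPI vesicle coat, was lower with CXCL14 (18786 against 6006 units, a difference of -1.54), and so was *ST14*, a membrane serine protease (876 against 338 units, -1.27). In the highest class of level, which holds *COPB2*, 1 of 3640 genes (0.03%) and 2 of 1910 repeated spots (0.10%) were at least 2-fold low. Such a drop was thus no more frequent among these genes than among single spots. In the class of *ST14*, 0 of 1490 repeated spots fell as far. Smaller differences, under 2-fold, were found for *SNORD114-17* (-0.86), *KIAA1671* (-0.75, with -0.26 to 0.67 from 3 other probes) and *SPEM2* (-0.63). The value of each gene in this paragraph, other probes aside, rested on 1 spot per array.

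Some genes were well above background on 1 array only, which gives a bound. *TNFSF15*, a TNF family ligand, was at least 15.3-fold higher with CXCL14 (9.4 against 330 units), *CFAP299* at least 5.16-fold higher and the B-cell gene *FCRLA* at least 2.52-fold higher. *RORB*, an orphan nuclear receptor gene, was at least 46.9-fold lower with CXCL14 (881 against 9.4 units), *RNF180* at least 6.18-fold lower and the pseudogene *COL6A4P2* at least 6.0-fold lower. Each of these bounds rested on 1 spot per array.

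Of the immediate early genes, 36 of 43 were measured. *EGR2* was at least 2-fold higher, 0 were at least 2-fold lower and 35 lay between, with 5 members at least 1.5-fold higher and 0 at least 1.5-fold lower. The list median was 0.19, against 0.04 for random lists of the same size and level, at the 100th percentile of 10000 such lists. With E1A spike-in scaling the median was -0.13, the only setting with another sign. The percentile was 100 in each of the 10 other settings that did more than move all genes by a constant, so that it was at its upper limit and shows no margin. The list did not rest on its leading genes: 31 of 36 members lay above the median of genes of their level, and without the 5 members of largest difference the median was 0.18, again at the 100th percentile. *KLF2* (0.44), *FOSB* (0.43), *TRIB1* (0.34), *JUN* (0.28) and *IER2* (0.28), named after their values were seen, were among the other members above 0.25. *MYC*, *ZFP36L2* and *MCL1* differed by 0.11, 0.01 and 0.01, and *DUSP4* was at -0.16. Among the targets of cAMP and CREB, 16 of 20 genes were measured, with 0 beyond 2-fold, and their median was 0.16 (99.97th percentile, and -0.16 with E1A spike-in scaling). *DUSP1*, *FOS* and *FOSB* led this list, and *PDE4D*, a cAMP phosphodiesterase, was at -0.35, with -0.25 and 0.07 from 2 other probes. The 10 measured members that it does not share with the immediate early genes had a median of 0.04, at the 58.2nd percentile.

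**Figure D2:**
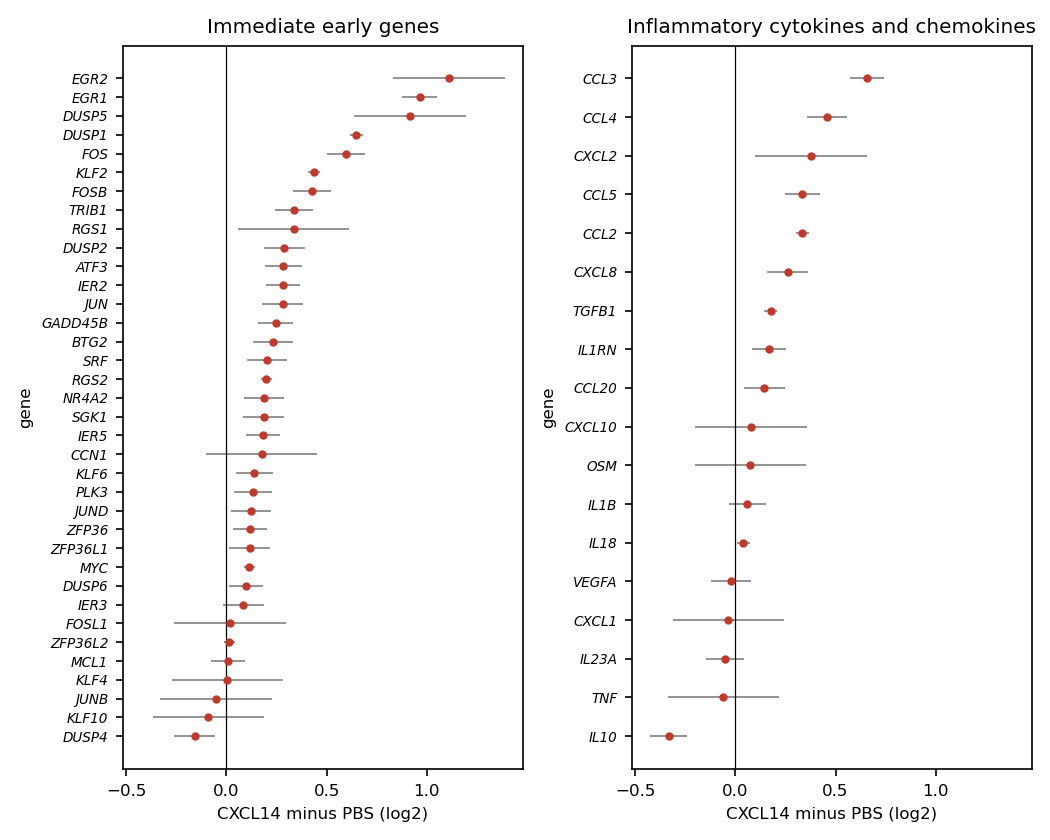
CXCL14 minus PBS (log2, x axis) for each measured immediate early gene (left) and each measured inflammatory cytokine or chemokine gene (right), 1 row per gene. Bars are the SD between repeated spots at the gene's level, divided by the square root of the gene's number of spots (technical error only, 1 array per group). *EGR2*, *EGR1* and *DUSP5* lie between 0.92 and 1.11, and *CCL3* leads the cytokines at 0.66 while *IL10* lies at -0.33. E1A spike-in scaling would lower each difference by about 0.32.

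Of the inflammatory cytokines and chemokines, 18 of 31 were measured and 0 were beyond 2-fold. Their median was 0.11, at the 98.8th percentile, between 91.9 and 99.98 in the other settings, and below 0 with E1A spike-in scaling (-0.21). *CCL3* and *CCL4*, which encode macrophage inflammatory proteins, were at 0.66 and 0.46, with 0.59 from another probe of *CCL4*. *CCL5* was at 0.33, and *CXCL2* at 0.38 with -0.25 from another probe. *TNF* and *IL1B*, which encode the classical cytokines of the acute response, were at -0.06 and 0.06, and *IL10* was at -0.33. The early targets of the NF-kB pathway (19 measured, 0 beyond 2-fold) had a median of 0.06 at the 68.0th percentile, and their members of largest difference were *TNFRSF9* (-0.21), *BCL2A1* (0.20), *CD40* (-0.19, but 0.00 with quantile normalization) and *NFKBIE* (0.18). Of the chemokine receptors, 12 of 24 were measured with a median of 0.11 at the 97.0th percentile, led by *CXCR2* (0.33), *CCR10* (0.21), *CXCR1* (0.17) and *CCR1* (0.17). The interferon-stimulated genes (30 measured, 0 beyond 2-fold) had a median of 0.06 at the 90.2nd percentile, with *IFIT2* at 0.46 (-0.20 from another probe), *OAS3* at 0.38, *OASL* at 0.26 and *ISG20* at 0.25. *CXCL2*, *TNFRSF9*, *CXCR1*, *OAS3*, *OASL* and *ISG20* were in the lowest class of level, on 1 spot per array. Their differences were 0.61 to 1.36 times the spot SD of 0.28 there.

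The receptors and scavengers to which CXCL14 has been linked were looked at whatever their values. *CXCR4*, the receptor of CXCL12, had a signal of 5411 units with PBS and 5608 with CXCL14, a difference of 0.15 over 10 spots per array (-0.17 with E1A spike-in scaling). *CXCL14* itself was dim (45.7 and 40.9 units, -0.06, but 0.09 with quantile normalization and 0.07 with level-dependent scaling). *ACKR3* was well above background with CXCL14 only, with 22.8 and 25.4 units at least 1.17-fold higher. The lowest signal well above background was 23.2 units with PBS and 17.5 with CXCL14, so these unequal limits alone can give that detection. Its difference of 0.25 was under the SD between spots of 0.28 in the lowest class of level. *ACKR2* was not well above background on either array.

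The monocyte markers (23 measured, 0 beyond 2-fold) had a median of 0.15 at the 99.78th percentile, between 94.4 and 99.95 in the other settings and below 0 with E1A spike-in scaling (-0.17). The granule genes *ELANE* and *MPO* were at 0.28 each, *VCAN* was at 0.26 and *CEBPD*, a myeloid transcription factor gene, at 0.21. Macrophage differentiation genes (21 measured, 0 beyond 2-fold) had a median of 0.09 at the 93.1st percentile, with the cholesterol exporter gene *ABCG1* at -0.49, the scavenger receptor gene *CD163* at -0.37, *CTSB* at 0.32 and *TREM1* at 0.25. *VCAN*, *ABCG1*, *CD163* and *TREM1* were in the lowest class of level, on 1 spot per array. Their differences were 0.89 to 1.77 times the spot SD of 0.28 there. Adhesion and migration genes (33 measured, 0 beyond 2-fold) lay at the middle of random lists, with a median of 0.06 at the 58.6th percentile. The integrin genes *ITGB5*, a dim gene that turned to -0.11 with normexp background correction, and *ITGB1* were at 0.43 and -0.22, *ICAM2* was at 0.33 and *PXN* at 0.22.

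The replication-dependent histone genes, whose transcripts accompany DNA synthesis, had a median of 0.18 over 19 measured members, at the 100th percentile, and 19 of 19 lay above the median of genes of their level. Their percentile was at least 99.89 in the other settings, and the median was -0.14 with E1A spike-in scaling. *H3C2* was at 0.30, and *H2AC8*, *H3C10* and *H2AC11* were at 0.25 each. Several members of a histone family have similar sequences, and whether their probes share transcripts was not tested. S phase genes (28 measured) had a median of 0.08 at the 59.0th percentile, with *CDC6* at 0.57, *CDT1* at 0.25, *MCM5* at 0.21 and *MCM2* at 0.18. G2 and M phase genes (27 measured) had a median of 0.03 at the 5.16th percentile, with *CDC20* at 0.22, *AURKB* at 0.19, *CDC25B* at 0.17 and *PLK1* at 0.15. In both cell cycle lists and the histones 0 members were beyond 2-fold.

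Stress responses lay within the range of random lists. Heat shock proteins (19 measured) had a median of 0.08 at the 37.3rd percentile, with the co-chaperone gene *BAG3* at 0.53, *DNAJB4* at -0.34, *HSPA6* at -0.28 (0.12 from another probe) and *HSPE1* at 0.26. The unfolded protein and integrated stress response (25 measured) was at 0.10 and the 85.2nd percentile, with *EDEM1* at -0.38, *PPP1R15A* at 0.26, *SESN2* at 0.25 and *CRELD2* at 0.23. Targets of p53 (19 measured) were at 0.07 and the 90.2nd percentile, with *CDKN1A* at 0.37 and *BAX* at 0.37 (-0.04 from another probe). *RRM2B* was at 0.28 with -0.69 from another probe, and *BTG2* was at 0.23. The oxidative stress and metallothionein genes (22 measured) were at 0.10 and the 75.1st percentile, with *TXN* at 0.19, *FTL* at 0.18 (-0.03 and 0.04 from 2 other probes) and *MT1F* at 0.17. None of these 4 lists held a member beyond 2-fold. *BAG3*, *DNAJB4*, *HSPA6*, *EDEM1*, *CDKN1A* and *RRM2B* were in the lowest class of level, on 1 spot per array. Their differences were 1.01 to 1.89 times the spot SD of 0.28 there.

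Metabolic lists lay within the central 95% of random lists of their level, and the housekeeping genes lay just above it. Hypoxia and glycolysis genes (26 measured) were at 0.08 and the 81.3rd percentile, with *P4HA2* at 0.40, the glucose transporter gene *SLC2A1* at 0.27, *PKM* at 0.24 and *P4HA1* at 0.23. *P4HA2* was in the lowest class of level, at 1.42 times the spot SD of 0.28 there. Cholesterol synthesis and uptake genes (23 measured) were at 0.06 and the 19.0th percentile, with *MVD* at 0.25, *PMVK* at 0.22 and *EBP* at 0.20. Ribosomal protein genes (53 measured) had a median of 0.14 and random lists of their level 0.13, which put them at the 91.9th percentile. *RPS20* was at 0.30, *RPL9* at 0.26, *RPL8* at 0.25 and *RPL15* at 0.24 (-0.11 from another probe). Mitochondrial respiratory chain genes (39 measured) were at 0.13 and the 83.6th percentile, led by *UQCRH* (0.28), *NDUFA1* (0.26), *NDUFA9* (0.25) and *COX5A* (0.23). The housekeeping genes (20 measured) were at 0.15 and the 98.3rd percentile, with *RPL13A* at 0.20, *GUSB* at 0.18 and *GAPDH* at 0.17. They lay above the central 95% of random lists in 3 of the 10 other settings that did more than move all genes by a constant. None of these 5 lists held a member beyond 2-fold.

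Markers of other cell types were dim and did not stand apart. Lymphocyte markers (11 of 21 measured) had a median of -0.05 at the 23.9th percentile, with *BLK* at 0.74, *CD3E* at -0.54, *GZMB* at -0.38 and *CD8A* at -0.20 (-0.46 from another probe). Erythroid and platelet markers (9 measured) were at -0.06 and the 17.2nd percentile, with *ITGA2B* at -0.34, *ALAS2* at -0.33 and *HBG1* at -0.15. Epithelial, fibroblast and endothelial markers (9 measured) were at 0.00 and the 46.6th percentile, with *CLDN4* at -0.50, *VWF* at -0.46 (-0.17 from another probe), *CLDN5* at 0.27 and *COL1A1* at 0.15. In these lists 0 members were beyond 2-fold.

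**Figure D3:**
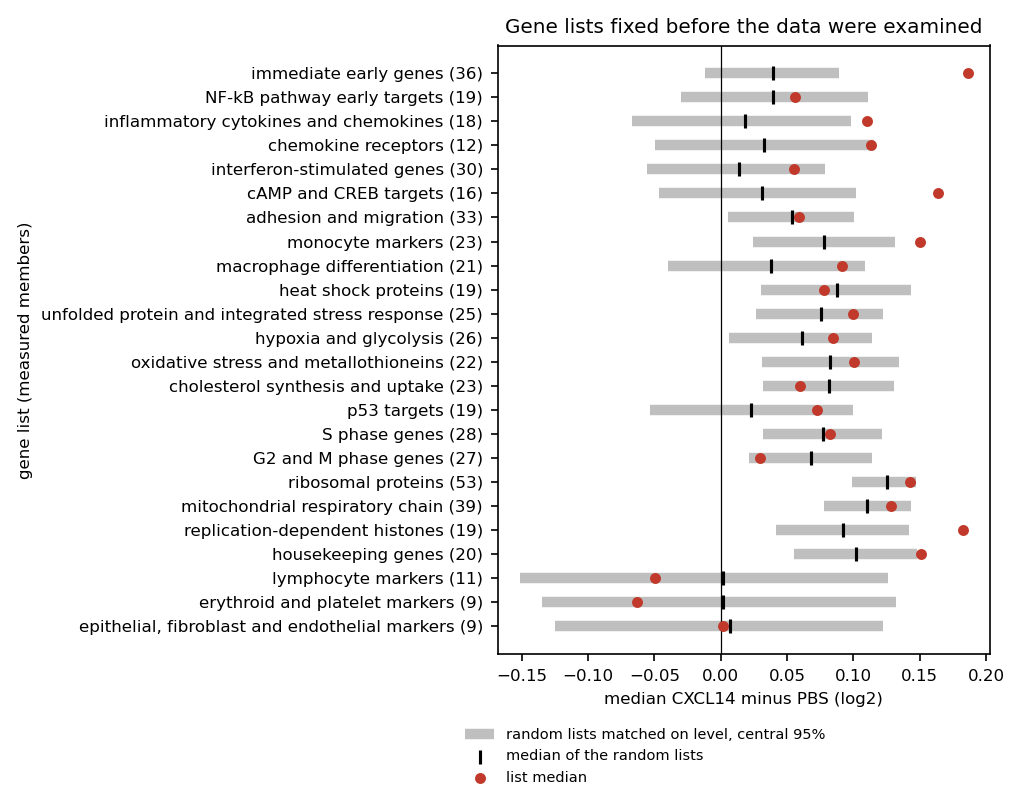
Median CXCL14 minus PBS (log2, x axis) of 24 gene lists (y axis, with the number of measured members), as red points, against the central 95% (grey bars) and median (black ticks) of 10000 random lists of the same size and level. Immediate early genes (0.19), histones (0.18) and targets of cAMP and CREB (0.16) lie furthest beyond their bars, and with E1A spike-in scaling all 24 medians lie below 0.

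With E1A spike-in scaling all 24 list medians lay below 0, and 12 of the 24 had another sign than above in at least 1 setting besides it. These 12 were the lists of NF-kB targets, interferon-stimulated genes, adhesion, p53 targets, chemokine receptors, heat shock, unfolded protein response, cholesterol, G2 and M phase, ribosomal proteins, lymphocytes, and epithelial, fibroblast and endothelial markers. Random lists treat genes as independent, so a percentile describes these 2 arrays and is not a test of the treatment.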

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

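Of the tests in this part, those of the immediate early genes without their 5 leading members and of the gene counts after level-dependent scaling were chosen after the results were seen. Probes without a gene symbol, which entered no comparison above, also differed: 18 of 8115 measured ones were at least 2-fold higher with CXCL14 than with PBS, and 55 were at least 2-fold lower. Of these, 1 higher and 0 lower probes were at or above the 25th percentile of gene level.

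The pattern most open to follow-up is the shift of the immediate early genes, with *EGR1*, *EGR2*, *DUSP1*, *DUSP5* and *FOS* at its head. Random lists of the same level carry a level-dependent shift between the arrays too, and the list median lay at their 100th percentile. That argues against such a shift as the cause. After level-dependent scaling the percentile was again 100, but that scaling moves a list and its random lists alike. It could hardly have changed the percentile and is no further evidence. Independent noise of single spots is argued against for the list as a whole, because random lists carry that noise too and the list without its 5 leading members also lay at the 100th percentile. The check planned before the data did not back this: the 6 other probes of 4 members gave a median of 0.01, at the 68.08th percentile, as noise would. Those of *NR4A2* and *IER3* were at -0.24 and -0.21 and that of *ZFP36L1* at 0.18. Those of *ATF3* were at -0.10, 0.12 and 0.65. They cover none of the 5 leading genes, but do cover members of the list without them. So few probes cannot decide. A difference in how the 2 cultures were handled cannot be told apart from CXCL14, since each group was 1 culture; the heat shock list at the 37.3rd percentile speaks only against a heat shock, and an early response to CXCL14 stays a hypothesis beside it.

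A second pattern was the excess of genes at least 2-fold lower (26, against 13 higher), of which 24 were in the lowest 25% of gene levels. The excess may come from a level-dependent shift between the arrays: after level-dependent scaling 16 genes were lower and 20 higher. A difference in background could not be excluded, because the genes lie near the floor. They had lost a median of 43.68 intensity units against 16.7 units for 3 SD of the PBS array's negative controls. That comparison cannot decide, since the selection fixed its outcome. A gene well above background on both arrays and at least 2-fold lower had to lose more than 16.7 units, and all 26 did. Noise of single spots stays open as well. In that class 0.659% of genes were at least 2-fold lower, and 0 of 1280 repeated spots deviated as far in that direction. That share is at most 0.299% (Wilson 95% interval), but a difference between single cultures cannot be set against array noise alone. In the other direction 0.33% of these genes were at least 2-fold higher, and 4 of 1280 repeated spots (0.31%) deviated as far. Such rises among dim genes, *EGR2* included, were thus about as frequent as among single spots. No biological explanation was tested.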

How the results depend on the processing

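All alternatives were planned before the data were examined, except E1A spike-in scaling and the 2 that left out list members (the cAMP and CREB targets at 0.04 and the immediate early genes at 0.18). Counts of genes at least 2-fold higher and lower (13 and 26) stayed within 1.5 times with median scaling, all spike-in controls (14 and 22), the mean over probes and outlying spots kept. They were 1 and 2 with normexp, whose offset compresses dim differences, 20 and 15 with quantile normalization, 20 and 16 with level-dependent scaling, and 6 and 123 with E1A spike-in scaling, where the whole distribution moved by -0.32. In the values of the authors, 12 were higher and 42 lower. Looser filters let in dimmer genes: 174 and 911 with no filter, 56 and 167 with 1 array well above background, and 91 and 469 with positive and significant signals. Above the median level 0 and 1 were left. Thresholds of 1.5-fold and 3-fold gave 68 and 183, and 3 and 1. The SD over genes (0.20) was 0.44 with no filter and 0.36 with positive and significant signals, and otherwise moved by less than the SD between repeated spots of 0.15, which was used in place of a replicate SD. Of 1378 values of named genes under the alternatives 1317 kept their sign, 204 moved by more than their spot SD, and 0 of those at least 2-fold apart changed sign. Of 288 list medians, E1A spike-in scaling aside, 67 moved by more than the error of a median at that spot SD. The signal over background limits the dim genes: the SD of the difference was 0.30 in the lowest 25% of gene levels and 0.11 in the highest 25%.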

Other observations

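The repeated probes give a view of the array itself. Over 653 probes spotted 10 times and well above background, the median difference was 0.06 and ranged over 4 classes of level from -0.0048 to 0.10, against -0.06 to 0.09 for genes. Of the immediate early genes, 5 were measured with 9 or 10 spots: *DUSP1*, *KLF2*, *RGS2*, *MYC* and *ZFP36L2*, at 0.65, 0.44, 0.20, 0.11 and 0.01. Of the inflammatory cytokines and chemokines, 5 were measured so: *CCL2*, *TGFB1*, *IL1B*, *IL18* and *IL10*, at 0.33, 0.18, 0.06, 0.04 and -0.33. These genes were taken for their number of spots after their values were seen.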
